A study of Homo sapiens with 37 samples.

How the data were processed

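The data were 1 matrix of estimated counts for 60,675 genes and 37 libraries. Per the submitters' processing notes, STAR 2.5.1b and RSEM 1.2.28 were used with the hg38/GRCh38 build. The order of the steps, the annotation release and the use of strand are not given in the sources used here. Without strand use, reads of overlapping antisense genes cannot be told apart. The deposited values are RSEM expected counts with 2 decimals, and 22.4% of the values above 0 were not whole (tolerance 0.005, 7.18% of all values), so they were rounded before the count models. A value that is not whole means that reads were split between genes, and the level of such a gene is less certain. Of 129 genes whose change the text gives, 15 had values that were not whole in all 37 libraries, namely TAGLN, GDF7, MSMP, TPM4, TPM1, DUSP6, MAP2K1, SREBF2, HSD17B7, LDHA, CD68, VWF, GIMAP1, GIMAP5 and MT-ATP6. MAPK1 and MAPK3 were whole in all.

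Columns were matched to samples by the library code in the labels. Of the gene identifiers 57,055 (94%) were matched to GENCODE release 29, which gave the coordinates on GRCh38. Symbols were those of the deposited matrix. XIST, TSIX and genes placed on the Y chromosome by this match or by their identifier (517 rows) were left out before any step. Unmatched genes had no chromosome, so Y genes among them could not be recognised. In all libraries 29,680 genes had 0. Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0. Genes were kept by filterByExpr with the group, which left 13,632, and scaled by TMM. A quasi-likelihood F test of siERK1/2 against siSCR (model: group alone) was adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. At an adjusted p of 0.01, 8,517 genes passed, and 9,972 had an unadjusted p under 0.05. The common biological coefficient of variation was 0.103. Standard errors are the log2 fold change over the square root of F. CPM values are TMM-scaled, as mean and standard deviation over libraries. The size of changes was tested with glmTreat against a fold of 1.5.

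The gene lists and the rule for naming genes were written before the values were seen. Genes named were the 2 targets, up to 12 highest and 12 lowest in fold and 6 of smallest p among passing genes with a mean of at least 5 CPM, and up to 4 members of smallest p from each list. NOS3, EDN1, TGFB2, TGFBR1, KLF2, KLF4, CDH5, PECAM1 and VWF were added because the series is about quiescent endothelium. Lists with at least 5 tested members were compared with all other genes by camera (inter-gene correlation 0.01, adjusted over the lists), and again with the correlation estimated for each list. Fry tested each list by itself, not against other genes. Members were counted as higher or lower by the adjustment over all tested genes. When adjusted over the list alone, 8 in place of 7 TGF-beta genes and 3 in place of 2 cholesterol genes were lower. The ERK output score was the mean z score of the log2 CPM (prior count 2) of the list, and its correlation with MAPK1 and MAPK3 was tested with 100,000 permutations, two-sided. The plan had been all 19 siERK1/2 libraries. Because libraries 8 to 12 stood apart, the other 14 were used, a choice made after the values were seen.

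The analysis was first run on simulated counts with known changes (13,488 genes tested). It recovered 74%, 94%, 100% and 94% of 50 genes each at folds of 1.2, 1.5, 2 and 4, with 4.23% of the 213 called genes false. A raised list passed (adjusted p 2.8e-35) and 0 of 20 null lists did. Genes were simulated independently of each other, and few changed, against 71.3% of the genes tested in the real data. The simulation therefore does not show how the list test behaves with correlated genes, nor the share of false calls in the real data.

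The 10 most abundant genes took 6.81 ± 0.24% of counts in siSCR and 8.90 ± 0.63% in siERK1/2, and the mean TMM factors were 1.031 and 0.972. The spread between libraries was compared with counting noise as a chi-square per gene between pairs of libraries. The lowest value was 1.64 in siSCR and 1.48 in siERK1/2. It was 2.23 to 3.51 between siERK1/2 libraries 8 to 12, 21.5 to 35.8 between these and the rest, and 24.2 to 51.5 between siSCR 1 and the other controls. The 14 replicate numbers present in both groups gave no sign of pairing: residual correlations between libraries of the same number ran from -0.144 to 0.134 (median 0.023), and 1 library correlated best with its own number.

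Alternatives replaced the scaling (DESeq2 size factors, upper quartile, library totals), the low-count filter, the test (DESeq2, limma voom with quality weights), the model (replicate number as a block, 4 surrogate variables) and the libraries. Those without siERK1/2 libraries 8 to 12, without siSCR 1, within the 5 deeper libraries or the other 32, and with that depth set as a term were added after the values were seen. Reads, alternative transcripts and variants in the RNA were not analysed here, because counts per gene were used. Expression of the sex-linked genes named above was not looked at.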

Results

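ERK1 and ERK2 are the last kinases of the growth-factor cascade and switch on transcription when they are active. Endothelial cells that line a resting vessel divide little, hold tight junctions and release nitric oxide, and they can take on features of mesenchymal cells when this state is lost. Knocking down both kinases in cultured endothelial cells asks which of these transcript programmes depend on them. RNA was sequenced from human umbilical vein endothelial cells that had received siRNAs to both kinases (siERK1/2, 19 libraries) or a scrambled siRNA (siSCR, 18 libraries). A single siRNA product was used per kinase, so an effect of those siRNAs on other transcripts cannot be told from an effect of ERK1/2 loss.

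Library totals ran from 11,233,777 to 22,507,048 counts (median 13,616,503), with 18,687 to 20,839 genes detected per library. Totals fell into 2 sets, 5 deeper libraries of at least 19,065,760 counts (siSCR 23 and 24, siERK1/2 1, 3 and 4) and 32 libraries of at most 15,518,378. The first principal component carried 47.9% of the variance and separated the groups. On the second (10% of the variance), siERK1/2 libraries 8 to 12 lay at 28.4 to 31.1 and the other 14 siERK1/2 libraries at -14.0 to -6.59. One control, siSCR 1, lay at 43.2 on the third component (4.8%) and the other 17 controls at -13.1 to 3.5.

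**Figure D1:**
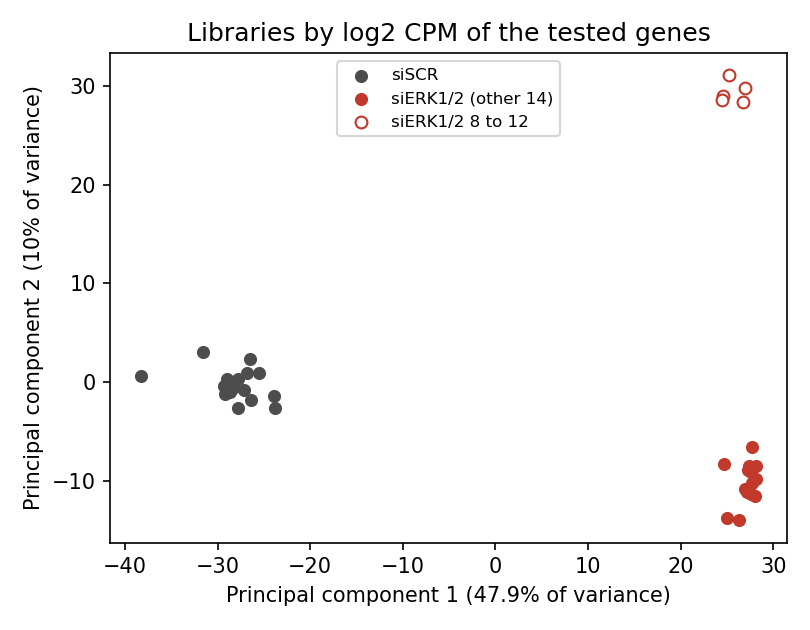
Libraries on the first 2 principal components of log2 CPM of the tested genes. Open circles are siERK1/2 libraries 8 to 12, which lay apart from the other 14 siERK1/2 libraries on component 2.

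Both siRNA targets fell in every siERK1/2 library, with no overlap with the controls. MAPK1, which encodes ERK2 (chromosome 22, 21,754,500 to 21,867,680), went from 183 ± 12.9 to 38.9 ± 7.43 CPM (mean ± SD), 4.71-fold lower (log2 fold change -2.24, standard error 0.068, adjusted p 2.328e-28). MAPK3, which encodes ERK1 (chromosome 16, 30,114,105 to 30,123,506), went from 74.4 ± 5.42 to 16.1 ± 2.66 CPM, 4.63-fold lower (log2 fold change -2.21, standard error 0.056, adjusted p 4.328e-31). Within the 5 deeper libraries the log2 fold changes were -2.23 and -2.19, and within the other 32 -2.23 and -2.20. MAPK1 ranged from 25.1 to 30.1 CPM in siERK1/2 libraries 8 to 12 and from 37.4 to 49.9 CPM in the other 14. Protein and kinase activity were not measured in these data.

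**Figure D2:**
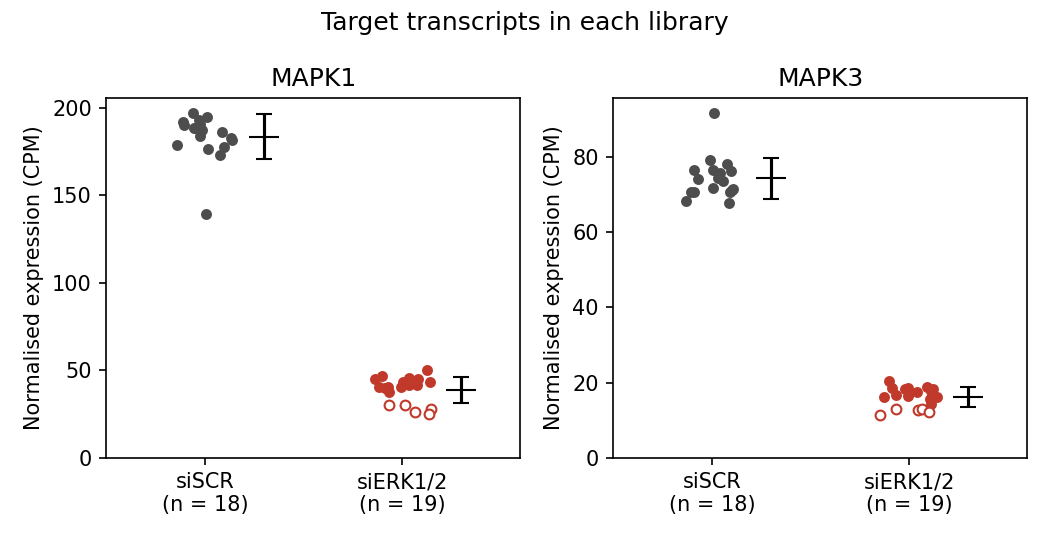
MAPK1 and MAPK3 in each library. Open circles are siERK1/2 libraries 8 to 12, in which MAPK1 ranged from 25.1 to 30.1 CPM.

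Of 13,632 genes tested, 9,713 (71.3%) changed at an adjusted p under 0.05, 4,651 higher and 5,062 lower in siERK1/2. Within the 5 deeper libraries 3,357 genes were higher and 3,201 lower, and within the other 32 libraries 4,631 were higher and 4,705 lower. Scaling to library totals alone gave 3,355 higher and 6,530 lower, so the balance of the directions depended on the scaling. Most changes were small: the median absolute log2 fold change of the changed genes was 0.28, and 404 genes were higher and 233 lower by at least 1 log2 unit. Against a fold of 1.5, 669 genes were higher and 384 lower. In 1,127 genes every siERK1/2 library was above every control, and in 991 every one was below. The labels do not state whether the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical.

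Folds were ranked among passing genes with a mean of at least 5 CPM. Of the 12 such genes with the largest increases, 5 were interferon-stimulated genes (RSAD2, IFIT1, IFI44L, IFI6 and MX1). Their increase lay mostly in siERK1/2 libraries 8 to 12. Among the other 7, GFRA1, a co-receptor for GDNF, rose 35.6-fold (0.284 to 10.5 CPM), the BMP-family ligands GDF7 and GDF6 22.3-fold and 10.8-fold, and the adhesion molecule CADM3 16.6-fold. FBLN5, an elastic-fibre protein, rose 15.6-fold, from 1.66 ± 0.46 to 25.9 ± 11.4 CPM. It was 8.66 CPM at most in siERK1/2 libraries 8 to 12 and reached 36.5 CPM in the other 14. GDF7, CADM3 and GDF6 were lower in those 5 too, at 42 to 52, 5.77 to 9.02 and 35.3 to 38.6 CPM. In the other 14 they were at 98 to 117, 13.3 to 17.6 and 47.1 to 67.3 CPM. The largest decreases included the immediate early factor EGR1 (24.4-fold lower, 10.3 ± 1.88 to 0.422 ± 0.388 CPM), the protease inhibitor SERPINB2 (21.1-fold lower) and the chemokine-like MSMP (27.9 to 3.50 CPM). EGR1 was 0.721 to 1.41 CPM in libraries 8 to 12 and 0.517 CPM at most in the other 14, and without the 5 it was 43.4-fold lower. The chemokine receptor CXCR4 fell 6.65-fold (56.3 to 8.42 CPM) and the endothelial lipase LIPG 5.13-fold (124 to 24.3 CPM). Among the genes with the smallest p-values, ANKRD1 rose 2.64-fold (835 ± 28.2 to 2,202 ± 72.1 CPM, adjusted p 2.322e-41), TPM4 2.12-fold and RND3 2.18-fold, while GIMAP4 fell 3.01-fold, HMGA2 from 216 to 72.0 CPM and CTSS 2.79-fold.

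**Figure D3:**
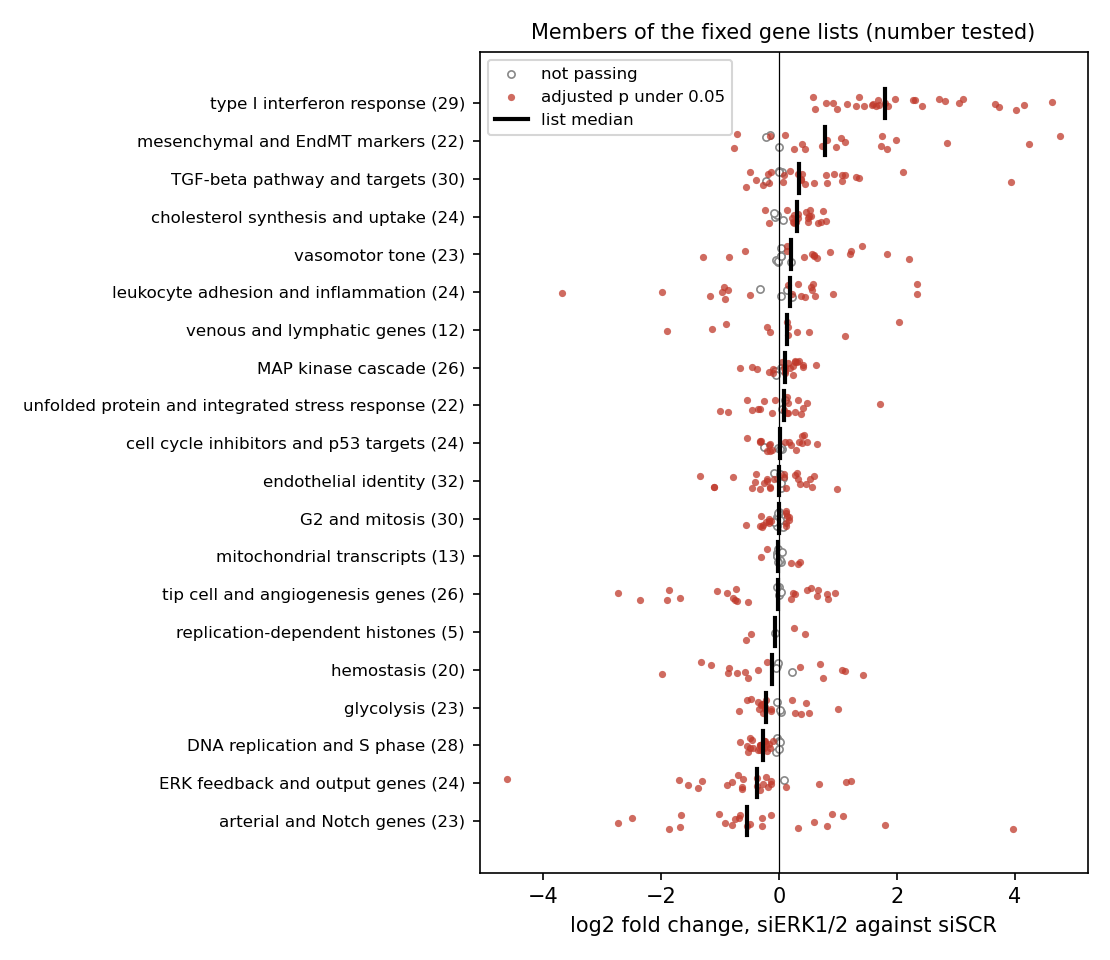
Log2 fold change of each tested member of the gene lists fixed before the values were seen, with the median of each list. Members of the ERK output list had a median of -0.38 and members of the mesenchymal list a median of 0.78.

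Genes transcribed downstream of ERK1/2 were lower as a set. Of 24 tested, 19 were lower, 4 higher (SPRY1, SPRY2, HBEGF and EPHA2) and IER3 did not pass. EPHA2 lost its call under library totals (adjusted p 0.0978). The list as a whole was lower than other genes (adjusted p over the lists 8.241e-05, median log2 fold change -0.38). With the inter-gene correlation estimated from the data the call was lost (adjusted p 0.0958), and without siERK1/2 libraries 8 to 12 it stood under that method too (0.0028). Besides EGR1, the transcription factors FOS and ETV4 were 3.23-fold and 2.59-fold lower. The MAP kinase phosphatases DUSP5, DUSP4 and DUSP6 were 2.90-fold, 2.46-fold and 1.53-fold lower. SPRY1, a feedback inhibitor of receptor signalling, was 2.33-fold higher, and the EGF-receptor ligand HBEGF was 2.20-fold higher. Genes named here and below that were neither extreme in fold or p-value nor among the leading members of a list were chosen after their values were seen. Of 26 other members of the MAP kinase cascade 16 were higher, 6 lower and 4 did not pass (ARAF, MAP2K2, RPS6KA2 and MAPK8), and the list did not pass against other genes (0.599). MAP2K1, which encodes MEK1, was 1.37-fold lower.

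Libraries 8 to 12, with the lowest MAPK1 of the siERK1/2 group, had its highest ERK output scores, from -0.28 to -0.08, against -0.75 to -0.39 in the other 14 and 0.18 to 0.86 in the controls. A correlation over all 19 would mostly reflect these 2 clusters, so it was taken over the 14, where neither target passed. Pearson r was 0.22 for MAPK1 (p 0.445) and -0.06 for MAPK3 (p 0.834), and in the 18 controls 0.16 (p 0.5) and -0.04 (p 0.866), with an adjusted p of 0.866 for all 4 relations. Without the deeper libraries r was 0.27 and -0.09 in 11 siERK1/2 libraries and 0.11 and 0.03 in 16 controls.

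Markers used for endothelial-to-mesenchymal transition were higher as a set. Of 22 tested, 16 were higher, 3 lower (TNC, TWIST2 and SNAI1) and 3 did not pass (FAP, COL3A1 and ZEB2), with a median log2 fold change of 0.78 (adjusted p 1.613e-10). The call was lost with the correlation estimated from the data (0.0816) and stood under that method without siERK1/2 libraries 8 to 12 (0.00014). TAGLN, a smooth-muscle actin-binding protein, rose 19.0-fold (18.2 ± 4.19 to 346 ± 53.6 CPM). COL1A2 rose 7.18-fold from a low level (1.27 to 9.17 CPM), MYL9 3.58-fold, CDH2 3.34-fold and COL5A1 3.31-fold. COL1A1, also in the list, was too low to test (0.566 in siSCR and 0.326 CPM in siERK1/2). ACTA2, the marker most often used, rose 1.19-fold (9.88 to 11.8 CPM) and did not pass without libraries 8 to 12 (adjusted p 0.869), and its log2 fold change was -0.02 in the 5 deeper libraries. SNAI1 did not pass without libraries 8 to 12 either (0.417). COL3A1 did not pass (12.1 to 10.9 CPM, adjusted p 0.223), but passed as lower under library totals (0.0449) and with surrogate variables (0.00828).

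TGF-beta ligands, receptors and targets were higher as a set: 19 of 30 were higher, 7 lower and 4 did not pass (TGFB3, BAMBI, SMAD6 and TGFBR2), with a median log2 fold change of 0.35 (adjusted p 9.372e-07). This call too was lost with the estimated correlation (0.133) and stood under it without libraries 8 to 12 (0.00014). TGFB2 rose 15.4-fold (18.4 ± 3.17 to 283 ± 32.5 CPM, adjusted p 9.816e-36), its receptor TGFBR1 2.56-fold, and the targets SERPINE1 and CTGF 2.18-fold and 1.75-fold. SMAD3 and ID1 were 1.32-fold and 1.40-fold lower. The list also held genes of the BMP branch (BMP2, BMP4, BMP6, ACVRL1, SMAD6, ID1, ID2 and ID3), so its counts and median are not those of TGF-beta alone.

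Endothelial identity genes did not move together. Of 32 tested, 12 were higher, 14 lower and 6 did not pass, with a median log2 fold change of 0 (adjusted p 0.985). VE-cadherin (CDH5) rose 1.24-fold, CLEC14A 1.98-fold, ROBO4 1.47-fold and VWF 1.28-fold. SOX18, CLDN5 and the VEGF receptor KDR were 2.53-fold, 2.15-fold and 1.72-fold lower, and PECAM1 did not pass (1,780 to 1,821 CPM, adjusted p 0.208). Arterial and Notch genes were lower as a set, 16 of 23 lower and 7 higher, with a median log2 fold change of -0.54 (adjusted p 0.00537). That call was lost with the estimated correlation (0.418) and without libraries 8 to 12 (0.325), where 16 were still lower and 7 higher and the median was -0.45. The target HEY1, whose mean was under 5 CPM, was 5.63-fold lower, the ligand DLL4 3.66-fold and the receptor NOTCH4 2.03-fold. IGFBP3 (2.11 to 7.35 CPM) and the ligand JAG2 were 3.49-fold and 1.87-fold higher. Of 26 sprouting genes 10 were higher, 12 lower and 4 did not pass (PLAU, LAMA4, ESM1 and INSR). The list was lower (0.0259), and the call was lost with the estimated correlation (0.133) and without libraries 8 to 12 (0.0684), with a median of -0.02 in all libraries and 0.01 without the 5. ANGPT2, which loosens vessels, fell 3.72-fold (312 to 84.0 CPM), MMP10 1.83-fold and PLAUR 1.69-fold. Venous and lymphatic genes, 7 higher and 5 lower (LYVE1, PROX1, TFF3, MMRN1 and NR2F2), did not pass as a set (0.460). TFF3 lost its call within the 5 deeper libraries (0.0573) and MMRN1 within the other 32 (0.066). RELN (1.11 to 4.59 CPM) and FLT4 rose 4.12-fold and 2.17-fold.

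Among 23 vasomotor genes 13 were higher, 3 lower (NOS3, EDNRB and ARG2) and 7 did not pass, and the list was higher (median log2 fold change 0.20, adjusted p 0.0203). The call was lost with the estimated correlation (0.333), without libraries 8 to 12 (0.169, median 0.11) and within the 5 deeper libraries (0.111). Endothelial nitric oxide synthase, NOS3, fell 2.43-fold (118 ± 14.6 to 48.6 ± 5.54 CPM), whereas endothelin (EDN1) rose 1.47-fold, PTGS2 1.82-fold and RAMP2 2.33-fold. The shear-responsive factors KLF2 and KLF4 rose 1.34-fold and 2.30-fold, and 1.15-fold and 1.62-fold without libraries 8 to 12, in which they were highest. Neither passed within the 5 deeper libraries (0.470 and 0.0708). Leukocyte adhesion and inflammation genes did not pass as a set: 12 of 24 were higher, 8 lower and 4 did not pass (LIF, NFKBIA, CCL20 and SELE), adjusted p 0.958. CX3CL1 and CCL2 rose 5.05-fold and 1.89-fold, while P-selectin (SELP) and CXCL1 fell 3.97-fold and 2.25-fold. Nor did the 20 hemostasis genes, 6 higher, 10 lower and 4 not passing (F2RL1, PLAU, ANXA2 and F8), adjusted p 0.985. SERPINE2 and thrombomodulin (THBD) rose 2.68-fold and 2.09-fold.

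Of 28 S-phase genes none was higher, 23 were lower and 5 did not pass (CCNE2, CDC45, RRM2, RAD51 and E2F1), and the list was lower (median log2 fold change -0.27, adjusted p 2.173e-06). The call was lost with the estimated correlation (0.256). The replicative helicase genes MCM3 and MCM7 were 1.58-fold and 1.44-fold lower. Controls also expressed such genes, for example MCM7 at 269 ± 18.8 CPM and the mitosis gene CDC20 at 233 ± 20.6 CPM, so these cultures were not shown to be resting. The 30 G2 and mitosis genes did not pass as a set (0.428), with 7 higher, 10 lower and 13 not passing. Under library totals none of the 30 was higher and 17 were lower. CDC20 was 1.48-fold lower. Nor did cell cycle inhibitors and p53 targets, 10 of 24 higher, 9 lower and 5 not passing (CDKN1C, GDF15, TIGAR, BBC3 and CDKN1B), adjusted p 0.781.

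Cholesterol synthesis and uptake genes were higher as a set. Of 24 tested, 18 were higher, 2 lower (DHCR24 and HSD17B7) and 4 did not pass (EBP, PMVK, NSDHL and HMGCR), with a median log2 fold change of 0.31 (adjusted p 0.0003525). The call was lost with the estimated correlation (0.418) and stood under it without libraries 8 to 12 (0.0037). HSD17B7 did not pass without those libraries (0.222). LDLR, the receptor for LDL uptake, rose 1.67-fold, LSS 1.58-fold and the transcription factor SREBF2 1.44-fold. Glycolysis genes did not pass as a set: 6 of 23 were higher, 14 lower and 3 did not pass (PFKFB4, PDK1 and PFKFB3), adjusted p 0.211. HK2 and LDHA were 1.61-fold and 1.39-fold lower and PFKP was 1.42-fold higher. Nor did 22 genes of the unfolded protein and integrated stress responses, 11 higher, 9 lower and 2 not passing (DDIT3 and CHAC1), adjusted p 0.599. ATF3 rose 3.28-fold and PHGDH fell 1.81-fold.

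All 29 interferon-stimulated genes tested were higher in siERK1/2, with a median log2 fold change of 1.80, but the list did not pass against other genes (adjusted p 0.0769, 0.990 with the estimated correlation). It passed under scaling to library totals (0.00734) and within the deeper libraries (7.872e-07) and the others (0.0463). It did not pass when only siERK1/2 libraries 8 to 12 were left out (0.373, and 0.957 with the estimated correlation). The deeper libraries hold none of those 5 either. Their controls, siSCR 23 and 24, had the lowest interferon scores (mean z score of the list) of all controls, -0.65 and -0.64. Most of the increase came from siERK1/2 libraries 8 to 12. IFIT1 was 157 to 212 CPM in those 5, 1.85 to 12.2 CPM in the other 14 and 1.12 to 5.45 CPM in the controls, and IFI6 was 1,151 to 1,349, 35.0 to 94.3 and 16.1 to 64.1 CPM. Without the 5 libraries 18 of the 29 were higher, 3 lower (OAS1, STAT1 and IFITM1) and 8 did not pass, and the median was 0.24. MX1 and IFI27 then had log2 fold changes of 1.12 and 1.15. Of the replicate numbers 8 to 12, the controls hold 9 and 12, and neither showed the increase.

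**Figure D4:**
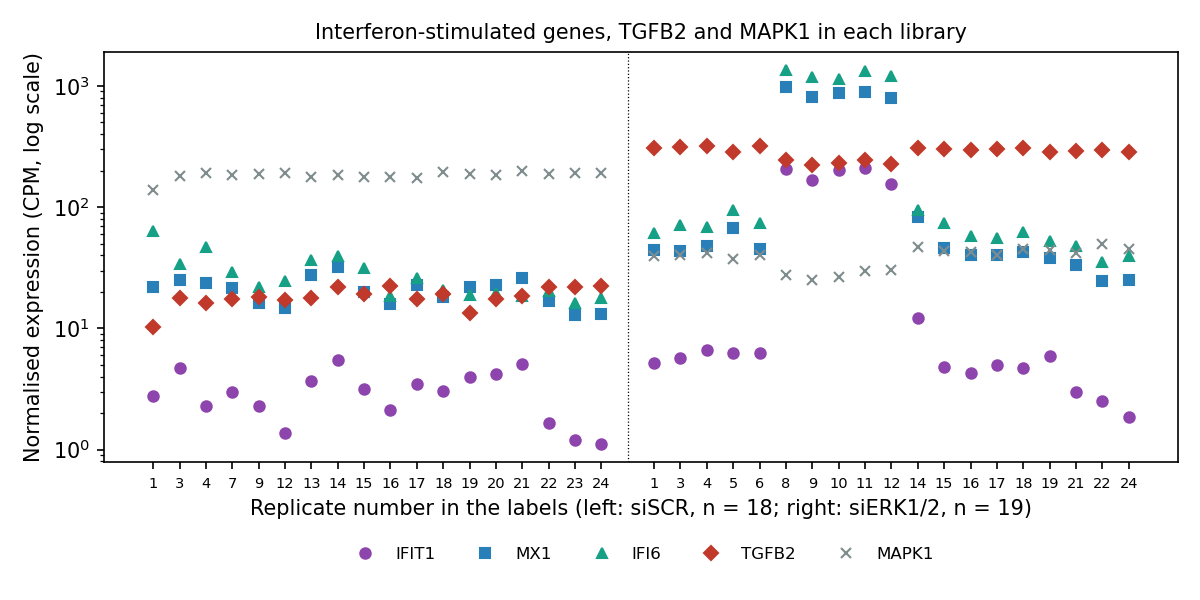
Interferon-stimulated genes, TGFB2 and MAPK1 in each library, in order of the replicate number in the labels. IFIT1 reached 157 to 212 CPM in siERK1/2 libraries 8 to 12 and 12.2 CPM at most in the other 14.

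Markers of other cells and of RNA quality gave these results. Of 4 stromal markers tested COL1A2 and LMOD1 were higher, RGS5 lower (284 to 161 CPM) and COL3A1 did not pass. The one leukocyte marker tested, CD68, was lower (18.8 to 13.1 CPM; 15.9 to 20.7 CPM in libraries 8 to 12 and 9.47 to 13.5 CPM in the other 14), no red-cell marker was expressed highly enough to test, and of 2 epithelial markers TACSTD2 was higher and KRT15 lower. Mitochondrial transcripts made up 2.45 ± 0.27% of counts in siSCR and 2.29 ± 0.36% in siERK1/2, with 1.58 to 2.04% in siERK1/2 libraries 8 to 12 and 2.01 to 2.96% in the other 14. MT-CO3 was 942 to 1,173 CPM in those 5 and 1,640 to 2,297 CPM in the 14. Of 13 mitochondrial mRNAs 3 were higher (MT-ND4L, MT-ND5 and MT-ND6), 2 lower (MT-CO3 and MT-ATP6) and 8 did not pass (adjusted p of the list 0.958). Within the 5 deeper libraries the mitochondrial list was lower (0.00558), and MT-ND5 and MT-ND4L had log2 fold changes of -0.04 and -0.16. MT-ATP6 lost its call without libraries 8 to 12 (0.379) and MT-ND4L under library totals (0.161). Of 5 replication-dependent histone transcripts, some of which are also made with a poly(A) tail, HIST1H2AC and HIST2H2BE were higher, HIST1H1C and HIST1H2AG lower, and HIST1H2BK did not pass (0.958). None of these 4 calls held throughout: HIST2H2BE and HIST1H2AC lost theirs under library totals (0.0986 and 0.0737), and HIST1H1C and HIST1H2AG within the 5 deeper libraries (0.602 and 0.152), where HIST2H2BE had a log2 fold change of -0.30.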

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

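The leave-outs of siERK1/2 libraries 8 to 12, of siSCR 1, and of either depth set, and depth as a term of the model, were chosen only after the values were seen. The fall of MAPK1 and MAPK3, the direction of the printed genes among the 12 highest and 12 lowest folds, and the number of genes changed (8,212 to 10,636, and 6,558 within the 5 deeper libraries) held. The replicate number as a block gave 8,988 genes, against 9,201 in the same 28 libraries without pairing. Over all settings 382 of 438 list results, 2,311 of 2,398 named-gene results and all target, fold-size and correlation results kept their call and direction. The cause of those that did not hold was not tested.

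Adjusted p-values of the lists follow. Camera with the correlation estimated lost every list call: ERK output 0.09584, mesenchymal 0.08161, TGF-beta and tip cell 0.1329, vasomotor 0.333, S phase 0.2557, arterial and cholesterol 0.4177. Without libraries 8 to 12 it still lost vasomotor and S phase (0.293), arterial (0.8431) and tip cell (0.132), and camera with the fixed correlation lost vasomotor (0.1688), arterial (0.3251, with the median moving from -0.541 to -0.454) and tip cell (0.06843). Vasomotor was also lost with the CPM filter (0.0694), voom (0.05047), numbers 15 to 24 (0.1308) and the deeper libraries (0.1113), tip cell with no filter (0.1021), voom (0.502) and numbers 15 to 24 (0.08224), and arterial with the last (0.1835). Fry, which tests a list by itself, called interferon (0.007123), MAP kinase cascade (7.385e-10), G2 and mitosis (0.03462), p53 (0.007505), venous (1.285e-07), glycolysis (2.318e-07) and stress responses (4.701e-05). Glycolysis passed with no filter (0.02031). Interferon passed with upper quartile (0.03404), library totals (0.00734), no filter (0.0001586), DESeq2 (0.007308), numbers 1 to 14 (0.001847), surrogate variables (5.54e-07), the deeper libraries (7.872e-07) and the other 32 (0.04626).

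Lists without a call turned direction, still without one, in these settings: endothelial with fry (0.7099), DESeq2 factors (0.9962), DESeq2 (0.9128), the shallowest libraries left out (0.9762) and the 32 libraries (0.9625), and hemostasis with DESeq2 factors (0.9962), no filter (0.5784), voom (0.6397), the same 28 libraries (0.9931), numbers 15 to 24 (0.7774), siSCR 1 left out (0.9985) and the deeper libraries (0.9201). The same held for histones with library totals (0.8713) and numbers 15 to 24 (0.9469), leukocyte adhesion with numbers 1 to 14 (0.8713) and mitochondrial mRNAs with surrogate variables (0.9813). In the deeper libraries mitochondrial mRNAs turned and passed (0.005581).

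Genes that turned direction, with log2 fold changes: IFITM1, OAS1 and STAT1, carried upward by libraries 8 to 12, were at -1.006, -0.55 and -0.169 without them, -1.16, -0.674 and -0.246 with numbers 15 to 24, and -0.545, -0.067 and -0.153 in the deeper libraries. IFITM1 and OAS1 were also at -0.478 and -0.174 with voom and -0.276 and -0.131 with the block. PECAM1 was at -0.052 with library totals and -0.008 with numbers 15 to 24, SNAI1 at 0.005 with the latter, MMRN1 at 0.025 with numbers 1 to 14, and COL3A1 at 0.037 without libraries 8 to 12 and 0.026 in the deeper libraries. In those ACTA2 was at -0.024, HIST2H2BE -0.297, MT-ND4L -0.158 and MT-ND5 -0.044. Genes changed by at least 1 log2 unit numbered 1,752 with no filter, and 3,201 genes were lower in the deeper libraries.

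Other gene calls that ended in at least 1 setting, with the direction kept there, were those of TFF3, NR2F2, MMRN1, KLF2, KLF4, F3, FJX1, TPM3, EPHA2, HSD17B7, SNAI1, ACTA2, STAT1, OAS1, IFIT1, RSAD2, MT-CO3, MT-ND4L, MT-ATP6 and all 4 histone genes. IFIT1 and RSAD2 did so only with numbers 15 to 24, which leave out libraries 8 to 12, KLF4 and TPM3 only in the deeper libraries, and EPHA2 only with library totals.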

Other observations

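The lists of YAP and TAZ targets, of actin and SRF targets and of the GIMAP family were chosen only after genes in them had been seen to change, while what each had to show was written before it was tested. Their genes are named by the same choice. ANKRD1 and TPM4 were among the increases of smallest p. ANKRD1 and CTGF (1.75-fold higher) are targets of the mechanically regulated factors YAP and TAZ, and TPM4, TAGLN and MYL9 belong to the actin and myosin apparatus that SRF and its cofactors control. Most other genes of both lists rose too. The actin list held mostly cytoskeleton genes. EGR1 and FOS, also controlled by SRF, were lower and were not in it. Nor was ACTA2, which did not pass without siERK1/2 libraries 8 to 12. The list therefore does not show a rise of SRF output in general. Of 24 other actin and SRF genes 22 were higher, TPM3 was lower, though not within the 5 deeper libraries (adjusted p 0.131), and LIMA1 did not pass (estimated-correlation p 5.654e-05, 2.881e-05 without siERK1/2 libraries 8 to 12). TPM1, FHL1 and MYH9 rose 2.51-fold, 2.31-fold and 1.68-fold. Of 16 other YAP and TAZ targets 12 were higher, 3 lower (F3, ARHGEF17 and FJX1) and MYOF did not pass (p 0.01533, 0.03567 without libraries 8 to 12), with CYR61 2.03-fold higher. FJX1 lost its call with DESeq2 size factors (adjusted p 0.0545) and F3 within the 5 deeper libraries (0.117). ERK1/2 loss may therefore put endothelial cells under more actin tension, and part of the mesenchymal and TGF-beta gene set, which shares targets with SRF and YAP, could follow from this rather than from a change of cell identity. Measuring stress fibres and the nuclear share of YAP and MRTF after knockdown, with and without a blocker of TGF-beta receptors, would tell the 2 apart.

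GIMAP4 was among the genes of smallest p and was lower. The GIMAP genes lie in a cluster on chromosome 7 and encode GTPases known mostly from lymphocytes. All 6 other tested members were lower as well (p 0.005096, 0.003665 without libraries 8 to 12), for example GIMAP7 2.05-fold and GIMAP8 2.02-fold. GIMAP5 (3.01-fold) and GIMAP1 (2.39-fold) are less certain, because their reads were partly split between genes in all 37 libraries. The cluster may hold a shared control element that needs ERK1/2 activity in endothelium. Chromatin accessibility over the cluster after knockdown would test this.

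For the patterns weighed next, the tests of knockdown alone for the interferon genes, and of stromal cells and of libraries 8 to 12 for the mesenchymal markers, were chosen only after the result was seen. The first pattern is the number of genes changed. The true grouping was 1 of 100 splits of the 37 libraries, and no other gave as many genes (highest 33, against 9,713). Other splits mix the groups and put their difference into the spread, and 96 of the 99 gave no gene. With groups this far apart the outcome was near certain beforehand. It sets the true grouping apart from a random division, but does not bear on the number of genes changed. Nor does it rule out a difference in culture or handling between the groups.

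Whether the knockdown alone gave the interferon increase in siERK1/2 libraries 8 to 12 cannot be told. Of the 5, 0 lay within the MAPK1 and MAPK3 ranges of the other 14. A response that starts only at a deeper knockdown of the target RNA therefore stays open. Their lower target RNA did not go with lower ERK output, however. The ERK output scores of the 5 (-0.28 to -0.08) lay above those of the other 14 (-0.75 to -0.39) and nearer to the controls (0.18 to 0.86). A line of the interferon score on MAPK1 over the other 14 libraries (r -0.304) left 5 of the 5 libraries above its 95% prediction interval. These 5 had been set apart because their values stood apart, so this outcome was likely beforehand. Their MAPK1 also lay below the range over which the line was fitted. The result shows only that the weak trend within the 14 does not reach the scores of the 5. Summed leukocyte markers, nearly all CD68, were higher in the 5 (16.3 to 21.6 CPM) than in the other 14 (9.64 to 13.9 CPM). The difference was only 0.101% of the rise in summed interferon transcripts. The controls had a similar sum (19.2 ± 2.6 CPM) without that rise, so the sum says little about leukocytes. The leukocyte gene PTPRC stayed at 0.149 CPM or less, which argues against leukocytes as carriers of these transcripts. Whether other cells set off the increase was not tested. A separate transfection in which double-stranded RNA was sensed could give this picture, and the labels do not say. Date of transfection and siRNA lot for each library would tell.

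The rise of mesenchymal markers could come from stromal cells in the cultures. Of the 15 stromal markers of the fixed list that had reads, 5 were higher in mean CPM (COL1A2, LMOD1, MYH11, ACTG2 and CSPG4). Most of the 15 were near the floor, for example TCF21 at 0.004 CPM and DES at 0.038 CPM in siSCR, so this count alone cannot decide. DCN and LUM, fibroblast markers of the list, went from 0.833 ± 0.261 to 0.181 ± 0.158 CPM and from 0.883 ± 0.310 to 0.136 ± 0.0893 CPM. They do not bear on smooth-muscle cells, whose markers were low and went both ways. MYH11 went from 0.269 ± 0.211 to 0.293 ± 0.165 CPM, LMOD1 from 0.347 to 1.14 CPM and DES from 0.038 to 0.002 CPM. Smooth-muscle cells in the cultures therefore stay open. The rise of the list was not made by libraries 8 to 12, since the list median without them was 0.886, against 0.78 with them. Under scaling to library totals the median was 0.693. Off-target effects of the siRNAs and differences between cultures remain open, because a single siRNA product was used for each kinase.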
